A study of Mus musculus with 4 samples.

How the data were processed

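Total RNA from liver was amplified and biotin-labelled with the manufacturer's whole-transcript kits and hybridised to Affymetrix mouse Gene 2.0 ST arrays, per the labels' protocols. The samples were 4, in 2 groups of 2: Western diet with ODH-08, and Western diet with vehicle. ODH-08 was suspended in 0.5% carboxymethyl cellulose, per the labels, and given after 16 weeks of diet. Groups and replicate numbers were taken from the sample titles.

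The authors deposited log2 values, 1 per probe set and array, made by RMA in Affymetrix Power Tools, per the submitters' processing notes; versions are not given in the sources used here. RMA corrects the background, gives all arrays 1 distribution by quantile normalization and then summarises probes by median polish. A change shared by most genes is therefore removed, dim probe sets are compressed towards a floor, and folds of dim genes understate the change. The table held 41345 probe sets and no detection calls, and scanner files were not used here. Column medians lay between 4.78 and 4.82 and the highest values between 13.6 and 13.7, and genes were not centred. Interquartile ranges of the deposited values were 2.81 and 2.80 for the ODH-08 arrays and 2.90 and 2.88 for the vehicle arrays. The summarised columns thus differed slightly in spread between the groups.

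Probe sets were named through the platform annotation given with the table. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none; 23328 of the first kind were matched by Entrez identifier to a RefSeq gene table (GRCm38.p6), which renamed 0. The 22180 genes so named were each represented by their brightest probe set over all 4 arrays. Genes whose mean lay at or above the 40th percentile of all probe sets (4.33 on the log2 scale) were tested, 15304 in all. Probe sets with several symbols or none entered only the alternative that tests all probe sets. No coordinates are given, since the sources used here name no genome build for the array.

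Each gene was fitted with limma (lmFit and eBayes, 2-sided, group as the only term), the contrast was ODH-08 minus vehicle, and p-values were adjusted over the 15304 genes by the method of Benjamini and Hochberg. A gene was called, and said to have risen or fallen, at an adjusted p under 0.05. The prior had 2.38 degrees of freedom and a standard deviation of 0.08, for 4.38 degrees of freedom in total. With 2 arrays against 2, an exact permutation test could not give a p below 0.333, so the calls rest on limma's pooled spread. Intervals are 95% intervals from the same fit. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists with at least 5 measured members, and the members of each list were also adjusted over the list alone.

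The 41 lists, the test, the filter, the rule for named genes and all alternatives but 1 were fixed before the data were examined. They covered lipid, bile acid, glucose and drug metabolism, mitochondria and stress, matrix and inflammation, growth, sex-biased genes, the clock, reported RORα targets, and markers of cell types that a piece of liver could hold. The rule named the 10 largest rises and 10 largest falls among called genes with no overlap between groups, leaving out predicted genes and small RNAs. It also named the 4 members with the smallest p of each called list and 1 of each other list, members that passed when adjusted over the list alone, and 15 genes chosen for RORα biology and fatty liver. Of those 15, 1 is not reported here. A few list members that did not pass were named beside them after their values were seen.

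The steps were tested on simulated data before use. In 20 simulated comparisons of ODH-08 with vehicle over 15304 genes, 200 of them changed, limma recovered 2.35% of genes changed by 0.5 on the log2 scale, 74.2% of those changed by 1 and 95.8% of those changed by 2, and 5.17% of its calls were genes that had not been changed. With no change built in, it called 0 genes on average. A list shifted by 0.5 was called in 20 of 20 runs, and any unshifted list in 1. The simulated genes were drawn independently of each other, so these runs do not show how often lists of correlated genes would be called wrongly. Their spreads were drawn from limma's own fitted prior with normal noise, so a low share of false calls was largely built in. The runs therefore cannot test whether that prior holds for these data. On the real arrays precision depended on brightness, which the simulation left out. There the median difference between the 2 arrays of a group was 0.17 for genes at levels of 4 to 6 and 0.03 at levels of 10 to 14.

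Alternatives changed 1 choice at a time: the filter (none, or the 60th percentile), the prior (intensity trend, robust, or none), the scaling (arrays centred on their medians, or quantile normalization again), array weights, the mean of a gene's probe sets, all probe sets, the replicate number as a block, each array left out, and the set test (an estimated correlation, a preset correlation of 0.05, ranks, or fry). Leaving members of multi-copy families out of the lists was added after the data were seen. R 4.3.3, limma 3.58.1, numpy 2.4.6 and matplotlib 3.10.9 were used.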

Results

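Whole-transcript expression was measured in the livers of male C57BL/6N mice, a common inbred laboratory strain, on Affymetrix mouse Gene 2.0 ST arrays. A Western diet, which causes fatty liver in mice, began at 7 weeks of age and lasted 21 weeks. For the final 5 weeks, 1 group was dosed by mouth with ODH-08, which the series' design text calls an agonist of RORα, and the other group is labelled vehicle. RORα, encoded by Rora, is a nuclear receptor that binds regulatory elements of clock and lipid genes. Each group had 2 arrays. The labels do not state that the arrays of a group came from separate mice, so the p-values measure only the spread between these arrays, which may be technical. Array medians lay between 4.78 and 4.82 on the log2 scale, and the number of arrays limits the precision of every value. Across the 15304 genes tested, which are not independent replicates, Pearson's r was 0.994 between the ODH-08 arrays, 0.995 between the vehicle arrays and 0.984 for each pair of arrays from different groups. The first principal component held 68.9% of the variance and separated the groups.

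The comparison of ODH-08 with vehicle asks which liver genes differ when the compound is given to mice already on the diet. By limma's camera at a preset correlation, the lists of male-biased and of fatty acid oxidation genes were higher with ODH-08, and 14 lists were lower, among them macrophage, matrix, inflammatory, acute phase, lipogenic and NRF2 target genes. None of these list calls held at an adjusted p under 0.05 in camera with an estimated correlation (smallest adjusted p = 0.17). In each list called at the preset correlation, some members passed gene by gene and others did not. In all, 549 genes passed the test, 150 higher and 399 lower with ODH-08 (limma, Benjamini-Hochberg adjusted p under 0.05), so 72.7% of the calls were lower. Of these, 146 differed by at least 2-fold, 32 higher and 114 lower. In each of the 549 genes, both ODH-08 arrays lay on one side of both vehicle arrays, an arrangement seen in 8104 of the 15304 genes tested, where chance gives it in 33.3% of genes. At an unadjusted p under 0.05 there were 3361 genes, where chance alone gives 765.2, and 574 of them differed by at least 1.5-fold, 136 higher and 438 lower. The median log2 difference over all genes tested was -0.003.

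Hsd3b5, a steroid-metabolising enzyme of male liver measured by probe set 17408315, showed the largest rise. Its log2 level was 9.62 ± 0.11 (SD, n = 2) with ODH-08 and 5.28 ± 0.29 (SD, n = 2) with vehicle, a 20.2-fold difference (log2 difference 4.34, SE 0.16, adjusted p = 0.0055). The other 9 largest rises were those of Moxd1 (3.96), Ugt2b38 (3.84), the pseudogene Serpina4-ps1 (2.41), the transcriptional repressor Bcl6 (2.33), Selenbp2 (1.86), Cyp7b1 (1.84), Slco1a1 (1.81), Cyp4a12b (1.77) and Slc22a7 (1.70), all as log2 differences. Bcl6 was at 8.33 ± 0.02 with ODH-08 and 5.99 ± 0.04 with vehicle (SD, n = 2 each), 5.03-fold higher (SE 0.06 on the log2 scale, adjusted p = 0.0055). Cyp2b9, a cytochrome P450 of female mouse liver measured by probe set 17475385, showed the largest fall, from 9.75 ± 0.00 with vehicle to 3.96 ± 0.57 with ODH-08 (SD, n = 2 each), or 55.3-fold (log2 difference -5.79, SE 0.28, adjusted p = 0.0077). After it came Ly6d (-3.52), Sprr1a (-3.37), Gpnmb (-3.21), Orm3 (-2.80), Saa2 (-2.72), Lcn2 (-2.72), Gstm3 (-2.63), Orm2 (-2.60) and Atp6v0d2 (-2.31). For Moxd1, Ugt2b38, Cyp2b9, Sprr1a and Atp6v0d2 the mean of the dimmer group lay under the filter level of 4.33, where the table holds no detection calls, so those folds depend on the dim end of the array.

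The number of calls rested on all 4 arrays. Limma called 1 gene without ODH-08 array 1, 1 without ODH-08 array 2, 0 without vehicle array 1 and 0 without vehicle array 2, with 2290 to 2724 genes at an unadjusted p under 0.05, and all 549 genes kept an unadjusted p under 0.05 in each of these 4 fits, which share arrays with the main one. The count was 0 with plain t statistics per gene (2671 genes at an unadjusted p under 0.05), 137 without the filter on dim genes and 2095 with an intensity trend in the prior.

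**Figure D1:**
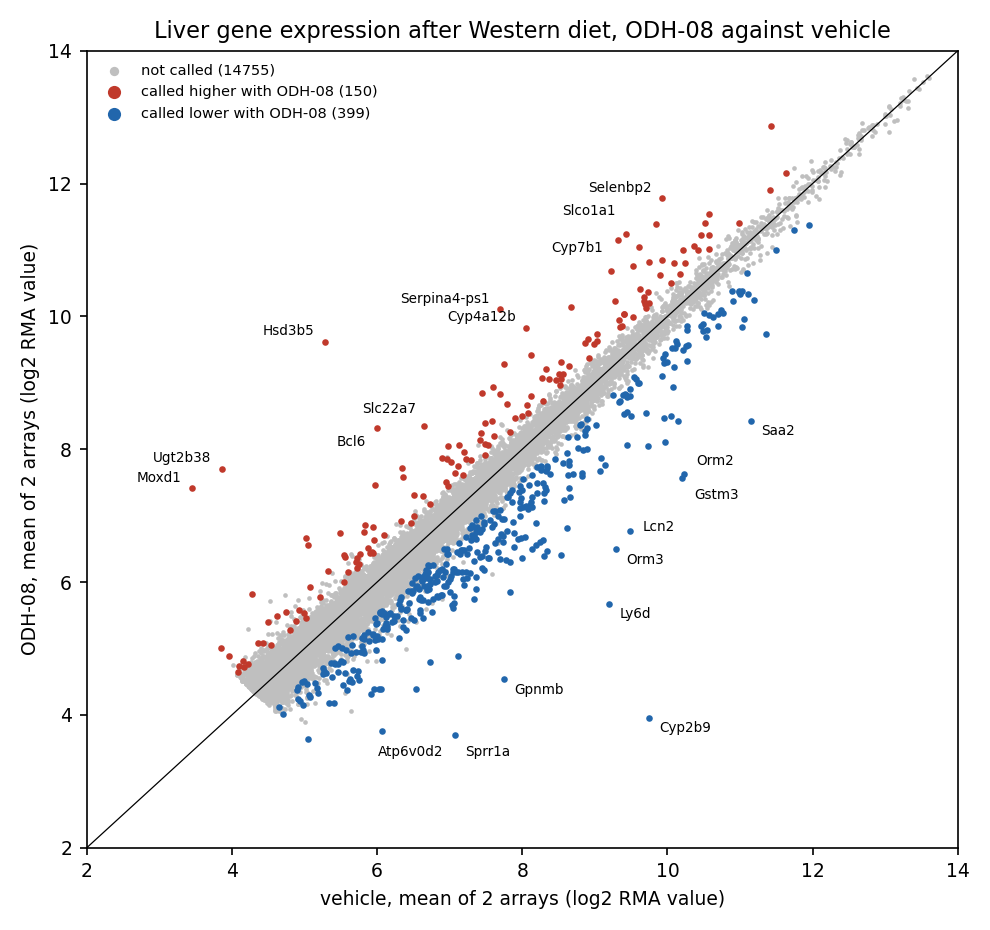
Mean log2 RMA value of each of the 15304 tested genes over the 2 vehicle arrays (horizontal) and the 2 ODH-08 arrays (vertical), with the line of equal values. Red points are the 150 genes that rose, blue points the 399 that fell and grey points genes that did not pass; the named points, among them Hsd3b5 above the line and Cyp2b9 below it, are the 10 largest changes in each direction.

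Of 41 gene lists fixed in advance, 40 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01. By that test 2 lists were higher and 14 lower with ODH-08. None of these 16 calls held with an estimated correlation, where camera called 0 lists and the smallest adjusted p was 0.17, although 7 lists had an unadjusted p under 0.05. That setting rests on the residual degrees of freedom of only 4 arrays, so few lists could pass it. The estimated correlation was under the preset 0.01 for some called lists, as for lipid-associated macrophage (-0.0005) and matrix (0.006) genes, and above it for others, as for lipogenesis genes (0.173). A call lost there is thus not by itself a sign of correlation between members. Fry, which asks only whether the members of a list move one way on balance and does not set them against other genes, called 32 lists. Each of the 16 lists was still called in all 4 fits that left out 1 array.

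Genes that are more abundant in male than in female mouse liver were higher as a list. Among 25 measured members of the male-biased list, 16 rose, 0 fell and 9 did not pass, and 22 differed when adjusted over the list alone, all of them higher. The median log2 difference was 0.97 (camera adjusted p = 1.3e-22, adjusted p = 0.17 with an estimated correlation). Most of the largest rises were on this list, but Bcl6, Serpina4-ps1 and Slc22a7 were not. Its other rises included the fatty acid elongase Elovl3 (0.97) and the growth factor receptor Egfr (1.43). The serine protease inhibitor Serpina1e (1.45) and the complement component C6 (0.70) rose too. The major urinary protein gene Mup20 (0.00, adjusted p = 0.99) and Mup3 (0.18, adjusted p = 0.21) did not pass.

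Genes that are more abundant in female liver moved mainly the other way. Of 20 measured members, 9 fell, 2 rose and 9 did not pass; adjusted over the list alone, 13 were lower and 2 higher. Their median log2 difference was -0.53 (camera adjusted p = 7.0e-06, adjusted p = 0.25 with an estimated correlation). After Cyp2b9, those that fell included the estrogen sulfotransferase Sult1e1 (-1.67), Cyp2b13 (-1.58), the peroxisomal transporter Abcd2 (-1.29) and the lipoprotein receptor Vldlr (-1.22). The 2 that rose were Cyp4a14 (0.89), which is also a target of the fatty acid receptor PPARα, and Cyp2c69 (0.84). Many members belong to multi-copy families whose near-identical genes can share probes. Outside those families, 6 of 10 male-biased genes rose and 3 of 6 female-biased genes fell. Among these falls, that of Atp6v0d2 (-2.31) is shared with the list of lipid-associated macrophage markers, which was lower. The Y-linked genes Eif2s3y, Kdm5d and Uty differed by -0.13 to 0.06 and did not pass, and Xist lay between 3.02 and 3.32 on all 4 arrays, under the filter level.

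In the de novo lipogenesis list, which was lower with ODH-08, 7 of 20 measured members fell, 0 rose and 13 did not pass, with 10 lower and 1 higher adjusted over the list alone. The list's median log2 difference was -0.23 (camera adjusted p = 7.0e-06, adjusted p = 0.31 with an estimated correlation). Fasn, the fatty acid synthase, fell 3.08-fold, from 11.36 ± 0.02 to 9.74 ± 0.02 (SD, n = 2 each; log2 difference -1.62, SE 0.06, adjusted p = 0.0055). Acly, which makes cytosolic acetyl-CoA, fell by 0.83, and Srebf1, which encodes the transcription factor that drives lipogenic genes, fell 1.65-fold (log2 difference -0.73, adjusted p = 0.017). The elongase Elovl6 (-0.61), Acaca (-0.57), Thrsp (-0.57) and Gpam (-0.51) also fell. Scd1 (-0.18, adjusted p = 0.22) did not pass.

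Fatty acid oxidation and PPARα target genes were slightly higher as a list. Of 29 measured members, 4 rose, 1 fell and 24 did not pass, with 7 higher and 1 lower adjusted over the list alone; the median log2 difference was 0.15 (camera adjusted p = 0.00016, adjusted p = 0.26 with an estimated correlation). The acyl-CoA thioesterase Acot1 (1.40), Cyp4a14 (0.89), the hormone gene Fgf21 (0.78) and the lipase inhibitor Angptl4 (0.45) rose, and Pdk4, a kinase that restrains pyruvate oxidation, fell by 0.80. Cpt1a, the enzyme of the carnitine step into mitochondria, differed by -0.02 (95% interval -0.19 to 0.14, adjusted p = 0.87).

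The remaining lipid lists were not called. In the lipid droplet list, G0s2, an inhibitor of triglyceride lipase, rose by 0.69, while the acyltransferase Mogat1 (-0.92), the fatty acid transporter Cd36 (-0.68) and the droplet protein Cidec (-0.51) fell, and 12 of 16 members did not pass (camera adjusted p = 0.37; 2 higher and 7 lower adjusted over the list alone). For lipoprotein assembly and export, Apom rose (0.59), Abcg1 fell (-0.68) and 18 of 20 did not pass (camera adjusted p = 0.49; 1 higher and 5 lower adjusted over the list alone). In the cholesterol synthesis and uptake list, Tm7sf2 rose (0.88), Insig1 (-0.67) and Hmgcs1 (-0.46) fell, and 17 of 20 did not pass (camera adjusted p = 0.72; 4 higher and 8 lower adjusted over the list alone). That list's median (-0.02) and mean (0.005) differed in sign.

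Bile acid synthesis and transport genes went both ways, and the list was not called (25 measured, median log2 difference 0.04, camera adjusted p = 0.22). The oxysterol hydroxylase Cyp7b1 rose 3.58-fold, from 9.31 ± 0.00 to 11.16 ± 0.01 (SD, n = 2 each; SE 0.06, adjusted p = 0.0055). The uptake carriers Slco1a1 (1.81) and Slc10a1 (0.54) and the sterol hydroxylase Cyp8b1 (0.44) also rose. The carrier Slco1a4 (-1.36) and both parts of the sterol exporter, Abcg5 (-0.70) and Abcg8 (-0.53), fell, and 18 members did not pass. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.39 and did not pass (adjusted p = 0.057), although it was among the 7 higher and 6 lower members that passed when adjusted over the list alone.

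In the list of NRF2 targets, genes switched on by the oxidative stress factor NRF2, 10 of 22 measured members fell, 0 rose and 12 did not pass, with 15 lower and 1 higher adjusted over the list alone. As a list they had a median log2 difference of -0.29 (camera adjusted p = 6.5e-09, adjusted p = 0.17 with an estimated correlation). The glutathione transferases Gstm3 (-2.63) and Gstm2 (-1.08), the quinone reductase Nqo1 (-1.02), Pgd of the pentose phosphate pathway (-0.82) and the heme oxygenase Hmox1 (-0.64) were among those that fell.

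For drug metabolism genes under the nuclear receptors CAR and PXR, 7 of 26 measured members fell, 1 rose and 18 did not pass, with 13 lower and 4 higher adjusted over the list alone. Their median log2 difference was -0.24 (camera adjusted p = 0.015, adjusted p = 0.26 with an estimated correlation). Cyp2b9, Cyp2b13, Cyp2a4 (-1.17) and Cyp2a5 (-1.06) fell, Cyp2c54 (0.64) rose, and Cyp2b10 (-0.53, adjusted p = 0.13) did not pass. The call held in 13 of 18 alternatives. Besides the estimated correlation, it was lost with camera on ranks, a preset correlation of 0.05, the strict filter and members of multi-copy families left out (adjusted p = 0.56 for the last). Of 5 measured aryl hydrocarbon receptor targets, Nqo1 fell and 4 did not pass (camera adjusted p = 0.46; 1 higher and 2 lower adjusted over the list alone).

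Of 20 measured markers of lipid-associated and monocyte-derived macrophages, which gather in fatty liver, 11 fell, 0 rose and 9 did not pass, with 17 lower and 1 higher adjusted over the list alone. The median log2 difference was -0.92 (camera adjusted p = 7.7e-14, adjusted p = 0.17 with an estimated correlation). Gpnmb, a membrane glycoprotein of lipid-laden macrophages, fell 9.25-fold, from 7.74 ± 0.11 to 4.54 ± 0.13 (SD, n = 2 each; log2 difference -3.21, SE 0.10, adjusted p = 0.0055). The elastase Mmp12 (-2.23), the tetraspanin Cd63 (-1.65), Lpl (-1.62) and the lysozyme Lyz2 (-1.48) fell as well, and Trem2 (-1.08) passed only when adjusted over the list alone.

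Resident Kupffer cell markers were also lower as a list, with 12 of 18 measured members falling, 0 rising and 6 not passing; adjusted over the list alone, 13 were lower and 1 higher. Their median was -0.87 on the log2 scale (camera adjusted p = 1.1e-09, adjusted p = 0.17 with an estimated correlation). Cd5l fell by 1.68, the complement components C1qb (-1.15) and C1qa (-0.99) fell, and Adgre1, which encodes a macrophage surface receptor, fell 2.06-fold (log2 difference -1.04, adjusted p = 0.012). The members were not alike: Clec4f (-0.27), Timd4 (-0.21) and Cd163 (0.79) did not pass. Some members that fell, such as Adgre1 and C1qb, are not restricted to Kupffer cells.

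Inflammatory cytokine and chemokine genes were lower as a list, with 12 of 27 measured members falling, 0 rising and 15 not passing; adjusted over the list alone, 16 were lower and 1 higher. The median log2 difference was -0.51 (camera adjusted p = 5.1e-08, adjusted p = 0.24 with an estimated correlation). Examples were the chemokines Cxcl9 (-1.30) and Cxcl1 (-1.12), the adhesion molecule Vcam1 (-1.21) and the inflammasome protease Casp1 (-0.93). Tnf differed by 0.19 (95% interval -0.06 to 0.43, adjusted p = 0.32).

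Within the acute phase list, 8 of 24 measured members fell, 0 rose and 16 did not pass, with 10 lower adjusted over the list alone; the median log2 difference was -0.20 (camera adjusted p = 7.0e-06, adjusted p = 0.26 with an estimated correlation). The falls were concentrated in Orm3, Saa2, the iron-scavenging lipocalin Lcn2 (6.58-fold, adjusted p = 0.0055), Orm2 and Saa3 (-1.40), and the list was not called without members of multi-copy families (adjusted p = 0.18). Interferon response genes were lower as a list, although only Gbp3 (-0.82) and Zbp1 (-0.55) of 27 measured members fell and 6 were lower adjusted over the list alone (median log2 difference -0.23, camera adjusted p = 0.00016, adjusted p = 0.25 with an estimated correlation).

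No other list of immune cells was called. In the B and plasma cell list, the antigen-presentation genes H2-Aa (-1.91), H2-Ab1 (-1.87) and H2-Eb1 (-1.23) and Cd22 (-0.53) fell and Derl3 (1.37) rose among 14 measured; 2 were higher and 5 lower adjusted over the list alone, and the median (0.07) and mean (-0.24) differed in sign (camera adjusted p = 0.48). T and NK cell markers had 1 fall, the chemokine gene Ccl5 (-1.47), among 20 measured (camera adjusted p = 0.20; 3 higher and 5 lower adjusted over the list alone). Neutrophil markers had 1 fall, Lcn2, among 6 (camera adjusted p = 0.22; 1 lower adjusted over the list alone). Dendritic cell markers had 0 calls among 13 (camera adjusted p = 0.18; 1 lower adjusted over the list alone). In the alternative macrophage activation list, the pattern receptor Clec7a (-1.97) fell and 11 of 12 did not pass, among them Klf4 (-0.36, 95% interval -0.94 to 0.22, adjusted p = 0.41) (camera adjusted p = 0.22; 1 higher and 3 lower adjusted over the list alone).

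**Figure D2:**
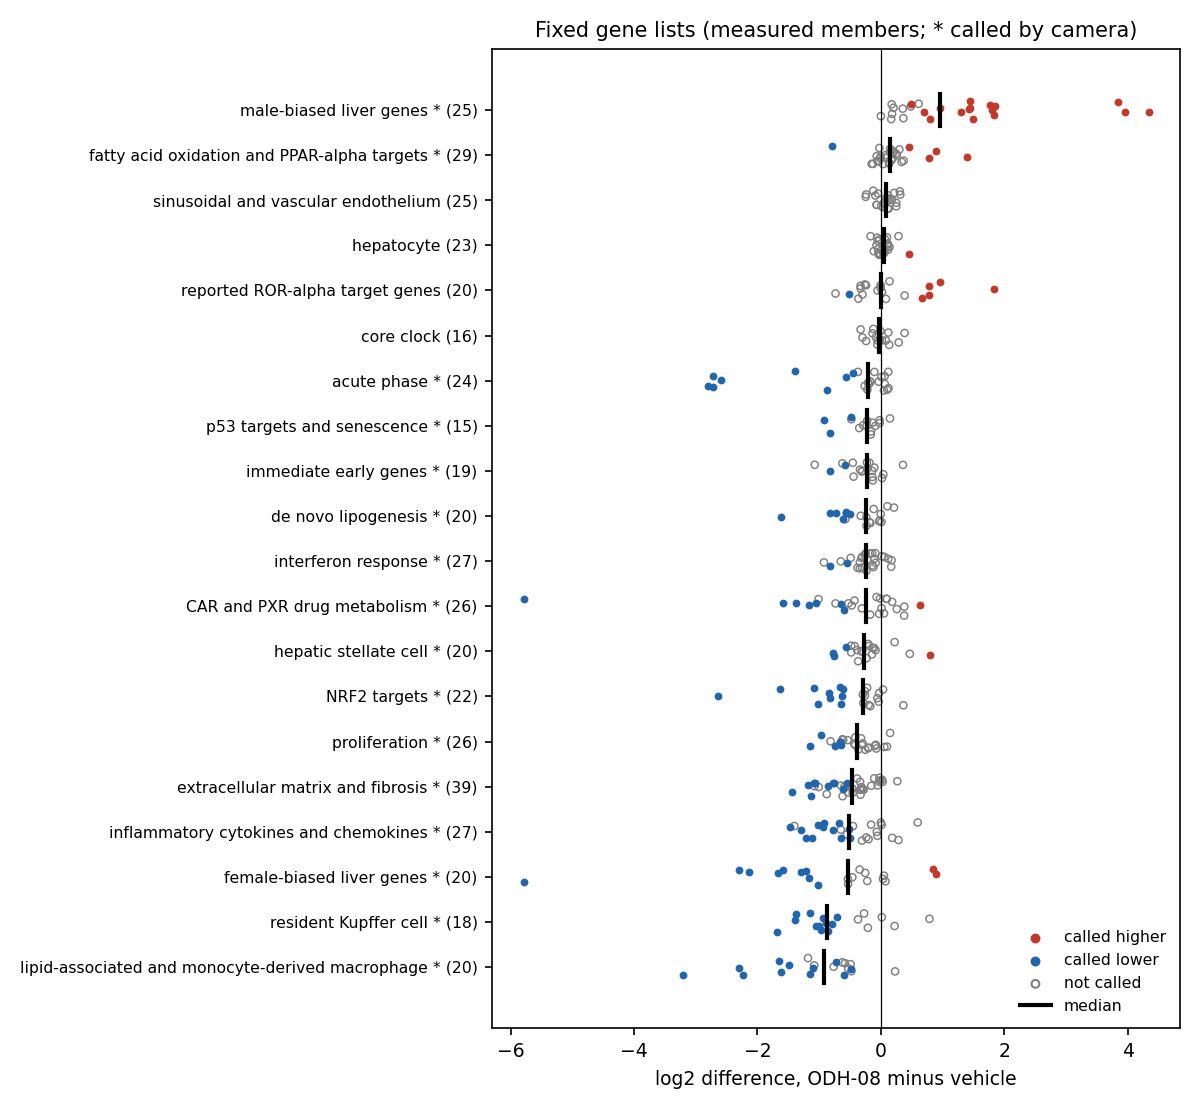
Log2 difference, ODH-08 minus vehicle, of every measured member of 20 fixed gene lists (1 point per gene, n = 2 arrays per group). Filled red and blue points are genes that rose or fell, open grey points genes that did not pass, black bars list medians, stars lists called by camera at the preset correlation, and numbers in brackets measured members; medians run from 0.97 for male-biased genes to -0.92 for lipid-associated macrophage markers.

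Of 39 measured members of the extracellular matrix and fibrosis list, 10 fell, 0 rose and 29 did not pass, with 24 lower and 1 higher adjusted over the list alone. The list's median was -0.46 on the log2 scale (camera adjusted p = 2.9e-12, adjusted p = 0.17 with an estimated correlation). The fibrillar collagens Col3a1 (2.71-fold, log2 difference -1.44) and Col1a1 (2.27-fold, log2 difference -1.18, adjusted p = 0.027) fell, as did the collagenase Mmp13 (-1.09), the matrix protein Dpt (-1.07) and Col14a1 (-0.86). Timp1 (-1.01, adjusted p = 0.070) and Acta2 (-0.15, adjusted p = 0.40), a marker of activated stellate cells, did not pass. The intermediate filament gene Vim fell by 0.77 on its brighter probe set, and its dimmer one differed by -0.19.

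Hepatic stellate cell markers had 3 falls, 1 rise and 16 members that did not pass among 20 measured, with 11 lower and 2 higher adjusted over the list alone (median log2 difference -0.27, camera adjusted p = 0.0005, adjusted p = 0.25 with an estimated correlation). Sparcl1 (-0.78), the retinol-esterifying enzyme gene Lrat (-0.76) and Colec11 (-0.57) fell, and the hedgehog-binding protein gene Hhip (0.80) rose.

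Markers of other cell types and of liver zones gave no called list. Endothelial markers had 0 calls among 25 measured and 0 adjusted over the list alone (median log2 difference 0.09, camera adjusted p = 0.054). That list was called, as higher, in 6 of 18 alternatives. In the hepatocyte list Serpina1a (0.46) rose and 22 of 23 did not pass, with 1 higher adjusted over the list alone (median 0.05, camera adjusted p = 0.20). Cholangiocyte and progenitor markers had 1 rise, Onecut1 (1.34), and 1 fall, Anxa5 (-0.94), among 12 (camera adjusted p = 0.18; 2 higher and 6 lower adjusted over the list alone). Pericentral hepatocyte genes had falls of Gstm3 and Cyp2a5 and a rise of Tbx3 (0.81) among 19 (median -0.009 with a camera direction of higher, adjusted p = 0.97; 4 higher and 5 lower adjusted over the list alone). Periportal hepatocyte genes had falls of Hsd17b6 (-1.18) and Aldh1b1 (-1.03) among 18 (camera adjusted p = 0.13; 1 higher and 6 lower adjusted over the list alone). Of 10 adipose genes, Fabp4 (-1.18), a lipid carrier also made by macrophages, fell (camera adjusted p = 0.37; 1 higher and 4 lower adjusted over the list alone). Pancreas genes had 0 calls among 7 (median -0.04, mean 0.01, camera adjusted p = 0.85; 1 higher adjusted over the list alone), and the erythroid list had 4 measured members, too few to test, of which Tspan33 (1.03) rose, the 1 member that was higher adjusted over the list alone.

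The proliferation, p53 target and immediate early lists were lower. Of 26 measured proliferation genes, 5 fell, 0 rose and 21 did not pass, with 14 lower adjusted over the list alone (median log2 difference -0.39, camera adjusted p = 5.1e-08, adjusted p = 0.25 with an estimated correlation). The replication helicase genes Mcm6 (-1.14), Mcm2 (-0.74) and Mcm3 (-0.64), the cyclin gene Ccnd1 (-0.96) and the proliferation marker Mki67 (-0.66) fell. Among 15 measured p53 targets and senescence genes, the cell cycle inhibitor Cdkn1a (-0.92), Btg2 (-0.82) and Phlda3 (-0.48) fell and 12 did not pass, with 5 lower adjusted over the list alone (median -0.22, camera adjusted p = 0.00037, adjusted p = 0.25 with an estimated correlation). In the immediate early list, Btg2 and Myc (-0.59) fell and 17 of 19 did not pass, with 7 lower and 1 higher adjusted over the list alone (median -0.22, camera adjusted p = 0.00016, adjusted p = 0.26 with an estimated correlation).

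The transcript of the receptor that the compound is said to activate did not differ detectably: Rora differed by -0.07 (95% interval -0.25 to 0.11, adjusted p = 0.62). Core clock genes had 0 calls among 16 measured (median -0.03, camera adjusted p = 0.87). Adjusted over the list alone, Clock (0.39) and Hlf (0.29) were higher and Arntl (-0.33) and Nr1d1 (-0.30) lower, and Npas2 differed by -0.24 (95% interval -0.95 to 0.47). Of 20 measured genes reported elsewhere as RORα targets, 5 rose, 1 fell and 14 did not pass, with 6 higher and 6 lower adjusted over the list alone; the list was not called (median -0.003, mean 0.13, camera adjusted p = 0.37). Cyp7b1 (1.84), Elovl3 (0.97), the glucose-releasing enzyme gene G6pc (0.79), Fgf21 (0.78) and the vasopressin receptor gene Avpr1a (0.67) rose, and Cidec (-0.51) fell. Fgf21 was 1.72-fold higher, at 7.81 ± 0.06 against 7.03 ± 0.05 (SD, n = 2 each; adjusted p = 0.019). Of the 20, 19 also stand in another of the fixed lists.

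**Figure D3:**
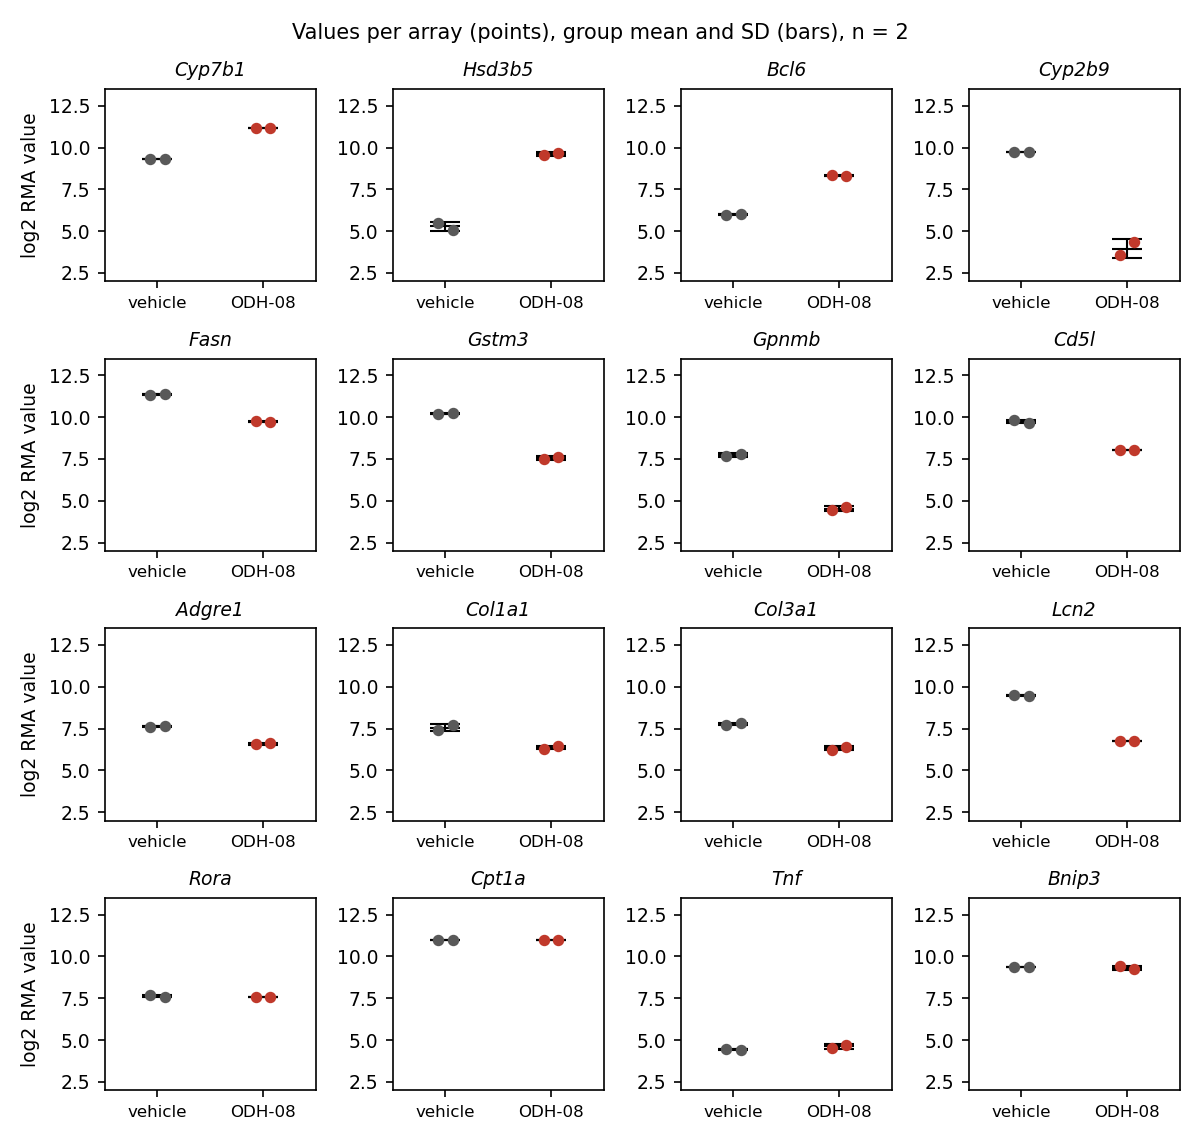
Log2 RMA value of selected genes on each of the 4 arrays (1 point per array, n = 2 per group), with bars for the mean and SD of each group. Some pairs of points lie close together, as for Bcl6 at 8.33 ± 0.02 with ODH-08 and 5.99 ± 0.04 with vehicle (SD). Others lie further apart, as for Cyp2b9 at 3.96 ± 0.57 with ODH-08 (SD). For Rora the groups differed by -0.07.

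Glucose, mitochondrial, lysosomal and protein-folding lists were not called. In the glucose metabolism list, G6pc (0.79) and Pfkfb3 (0.62) rose, Igfbp1 (-0.84) fell and 12 of 15 did not pass (camera adjusted p = 0.64; 2 higher and 1 lower adjusted over the list alone). Oxidative phosphorylation subunits had 0 calls among 38 and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.11). Mitochondrial quality control genes had 0 calls among 18 and 0 adjusted over the list alone (median 0.02, camera adjusted p = 0.57), with the mitophagy receptor gene Bnip3 at -0.05 (95% interval -0.28 to 0.17). In the autophagy and lysosome list, Gpnmb, the lysosomal protease gene Ctss (-1.55) and Hexa (-0.47) fell and 22 of 25 did not pass; 7 were lower adjusted over the list alone, and the median (0.02) and mean (-0.22) differed in sign (camera adjusted p = 0.37). Of 27 unfolded protein response genes, the folding factors Creld2 (0.95) and Hyou1 (0.48) rose, the chaperone gene Dnajb9 (-0.53) fell and 24 did not pass (median 0.08, camera adjusted p = 0.059; 6 higher and 4 lower adjusted over the list alone).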

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

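No test in this part was chosen after the result was seen. Probe sets that could not be given a single gene symbol stood outside the comparison of named genes, and some differed between ODH-08 and vehicle when limma tested all probe sets past the filter. Of 1159 tested probe sets with several gene symbols, 12 were called, 2 higher and 10 lower with ODH-08 (adjusted p under 0.05). The 2 higher, 17408297 and 17408306, had identical values (log2 difference 2.36), so they are not separate measurements. Of 7472 with no symbol, 20 were called, 8 higher and 12 lower. The largest rises among those with no symbol were of probe sets 17547945 (log2 difference 2.22) and 17445565 (2.04), and the largest falls of 17514340 (-2.29) and 17299101 (-1.89). These differences stand as values, and no explanation for them was tested.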

How the results depend on the processing

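Leaving members of multi-copy families out of the lists was chosen only after the result was seen. The count of 549 genes, 150 higher and 399 lower, stayed within 1.5 times under a robust prior (497), array weights (547), the mean of a gene's probe sets (534), repeated quantile normalization (562) and arrays centred on their medians (691), and 497 to 544 of the 549 calls were shared with each of these. Array weights could not tell the 2 arrays of a group apart, as both ODH-08 arrays had a weight of 0.92 and both vehicle arrays 1.08. With all probe sets past the filter tested, the count of calls was 139 (39 higher, 100 lower), among more features. Without a filter the count was 137 (33 higher, 104 lower), where dimmer genes were tested too. A filter at the 60th percentile gave 1007 (335 higher, 672 lower) and kept all 480 calls that it tested. An intensity trend gave 2095 (838 higher, 1257 lower), which lowered the share of lower calls from 72.7% to 60%; the cause was not tested. Plain t statistics, which drop the pooled spread, gave 0 genes in either direction (smallest adjusted p 0.067, 2671 genes at an unadjusted p under 0.05). Leaving out 1 array, with the lone array of its group assumed to vary like the other group, gave 0 to 1 genes, 0 higher and 0 to 1 lower, since fewer degrees of freedom were left.

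The shared replicate numbers showed no pairing across genes: the differences between replicates 1 and 2 in the 2 groups had r of -0.01. The lowest value was, however, the same on both replicate 1 arrays (0.949) and on both replicate 2 arrays (0.767). Shared handling by replicate number is thus not excluded. With the replicate number as a block, limma called 0 genes, 0 higher and 0 lower (smallest adjusted p 0.053, 3054 genes at an unadjusted p under 0.05), and the same number of lists, 16. The 574 nominal genes with a 1.5-fold difference became 1017 with all probe sets, of which more were tested, and ranged from 639 to 680 with 1 array left out.

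The 16 lists, 2 higher and 14 lower, became 0 (0 higher, 0 lower) with camera and an estimated correlation, which rests on few degrees of freedom. They became 32 (8 higher, 24 lower) with fry, which sets no list against other genes. An intensity trend gave 7 higher lists; the cause was not tested. Only the pericentral hepatocyte list, not called and higher by camera, turned round, being lower by fry (signed -log10 p of -2.43, adjusted p = 0.0075), as the tests ask different questions. Without multi-copy family members 14 lists were called, the acute phase and drug metabolism lists being lost. Dim signal limits the rest: the median difference between arrays of a group was 0.17 at levels of 4 to 6.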

Other observations

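The gene families described first, and the tests of Y-linked genes, endothelial markers, a uniform Kupffer cell loss and the difference between macrophage lists, were chosen only after the result was seen.

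Several cytoskeletal and membrane-binding genes fell with ODH-08; a few members of these families, such as Anxa5, S100a4 and S100a6, also stand in the fixed lists. They were lower alongside the macrophage markers below (median -0.92 for lipid-associated and -0.87 for Kupffer cell markers), and no test separated the families here from those. Of 10 measured annexins, which bind membranes in the presence of calcium, 3 fell and 0 rose, Anxa2 by 3.47-fold (log2 difference -1.80), and the family median was -0.45. Among 38 actin cytoskeleton genes 9 fell and 0 rose, including the actin-binding peptide gene Tmsb4x (-1.01), Iqgap1 (-0.94), the myosin gene Myh9 (-0.57) and the filamin gene Flna (-0.56), with a median of -0.18. Of 10 S100 genes 2 fell, S100a11 by 1.39, and of 12 tubulins 1 fell. The keratin genes Krt18 (-0.94) and Krt8 (-0.84), intermediate filaments of hepatocytes, fell too. Medians of the annexin and actin families were -0.48 and -0.21 with arrays centred, which shifts all genes by the same amount and so tests little. They kept their direction when arrays were quantile-normalized again (-0.46 and -0.20).

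Several receptors of innate immunity also fell, some of them members of the fixed lists. Of 6 measured Fc receptors and their adaptors 5 fell, with a median of -1.20, among them Tyrobp (-1.34), Fcgr1 (-1.23) and Fcgr4 (-1.18). Among 12 Toll-like receptors Tlr7 (-1.09), Tlr8 (-1.09) and Tlr13 (-0.92) fell, and of 8 MHC class II genes 3 fell (median -0.70). Terminal complement and coagulation genes of the hepatocyte had 3 rises, C8b (1.55), C6 (0.70) and F11 (0.57), and 1 fall, Pros1 (-0.43), among 19. By camera at the preset correlation, the 8 families had adjusted p-values of 8.9e-08 to 0.021, and each of them had adjusted p = 0.15 with an estimated correlation. Because the families were picked from their values, these p-values are descriptive.

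With ODH-08, 16 of 25 male-biased genes rose and 9 did not pass, and of 20 female-biased genes 9 fell, 2 rose and 9 did not pass. RNA of female mice among the vehicle arrays is argued against, because it would raise Y-linked genes with ODH-08 by about the male-biased median of 0.97, and the highest upper 95% bound of their differences was 0.29. Probes shared within multi-copy families are argued against as the whole cause by the members outside the families. Their median in the expected direction was 0.75 (95% bootstrap interval over genes 0.46 to 1.29). That interval treats genes as independent and holds no spread between arrays. An effect of the treatment and any other difference between the mice of the groups were not tested apart, and both stay open.

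With ODH-08, 11 of 20 lipid-associated macrophage, 12 of 18 Kupffer cell and 10 of 39 matrix genes fell, and each list had adjusted p = 0.17 with an estimated correlation. A lower share of all cells other than hepatocytes is argued against by the endothelial markers. Their median was 0.092 (95% bootstrap interval over genes 0.01 to 0.13). Lipid-associated and monocyte-derived macrophage markers had a median of -0.92 (-1.33 to -0.59). These bootstrap intervals treat genes as independent and hold no spread between arrays. One uniform loss of Kupffer cells stays open: 10 of 18 Kupffer cell markers had a 95% interval that excluded the list's median of -0.87, but so did 12 of 20 lipid-associated markers for theirs, and the intervals hold only the spread between arrays. The lipid-associated list lay below 10 markers restricted to Kupffer cells (median -0.32) by a difference of -0.60 (permutation test across genes, p = 0.023). Those 10 were chosen after the result was seen. The full Kupffer cell list had a median of -0.87, close to the -0.92 of the lipid-associated list. It also holds genes not restricted to Kupffer cells, such as Adgre1 (-1.04) and Cd68 (-1.38), so its median does not describe Kupffer cells alone. The difference thus depends on the choice of markers and cannot decide whether the loss was mainly of lipid-associated and monocyte-derived macrophages, which stays open. Lower expression per cell stays open, because RNA came from whole liver, in which these markers were not measured by cell type, and 2 of the 20 stand in other lists.

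The 2 arrays of each group lay close together. The 112 immediate early, acute phase, interferon, proliferation and clock genes were taken as genes that vary between animals. They differed between arrays of a group 1.07 times as much as 100 genes of like brightness (95% bootstrap interval over genes 0.88 to 1.16). For the 37 of them at a log2 level of 8 or more, the ratio was 1.03 (0.66 to 1.30), and for all 112 genes between the groups it was 2.20 (1.74 to 2.83). The immediate early, acute phase, interferon and proliferation lists were themselves called between the groups, so the last ratio does not bear on this question. Ratios within groups near 1 could arise if arrays held repeats of 1 RNA or pools of the same livers. In that case the p-values would measure technical spread. Noise of dim genes could also hide differences between animals, and the interval of the bright genes does not exclude them.

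The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split called 549 genes and the other splits 0, so only 1 of the 3 splits, the real one itself, called that many.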
